A study of Homo sapiens with 6 samples.

How the data were processed

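Gene expression was measured on 6 Affymetrix HuGene-1_0-st-v1 arrays, a 1-colour whole-transcript platform. The RNA came from MCF10A-HER2/3 cells, a line of the human mammary epithelial line MCF10A, grown in three-dimensional culture for 15 days. Cells carried a doxycycline-inducible lentiviral construct with a control miR, SHP2 miR1 or SHP2 miR2, and each of these 3 groups had 2 arrays. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

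The deposited values are the authors' processed probe set values on a log2 scale. Base 2 was inferred from their range, since the labels do not state it. R 2.10 and the oligo package 1.8 were used upstream, per the submitters' processing notes. The background correction, normalization, summary method and genome build are not given in the sources used here. Array medians lay between 5.23 and 5.35. The standard deviation over probe sets was 1.99 and 2.02 on the control arrays, 1.92 and 1.92 with SHP2 miR1, and 1.95 and 1.97 with SHP2 miR2. Replicates correlated at r = 0.986, 0.986 and 0.985 across genes, and no arrays held identical columns. Scan dates were not used here. The number of arrays limits the precision of every comparison.

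Of 28869 probe sets, 19310 had 1 gene symbol in the platform annotation, 1752 had several and 7807 had none. Only probe sets with 1 symbol were named. Of these, 19279 matched the RefSeq gene table by gene identifier, and 0 symbols needed updating. For the 685 genes with more than 1 such probe set, the probe set with the highest mean value was kept, which left 18377 genes.

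A linear model with the 3 groups was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3 and moderated with eBayes, with 3 residual and 6.10 prior degrees of freedom. Contrasts were the mean of both SHP2 miRs minus control, each SHP2 miR minus control, and SHP2 miR2 minus SHP2 miR1. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. All adjusted p-values of genes come from this limma fit. Differences on the log2 scale are given with the SE of the fit.

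The gene lists were written before the data were examined, as were the group comparisons, the list test, the rule for naming genes and the alternatives not marked as added. The 38 lists covered signalling outputs, proliferation, lineage, metabolism, stress and markers of 4 other cell types. They were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 38 lists. Camera with an estimated correlation and fry were run as alternatives. With an estimated correlation, camera tests on the 3 residual degrees of freedom of the fit, far fewer than at the preset. The median of each list was also ranked among 10000 random lists of the same size matched on mean value.

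Named genes follow a rule with 4 parts. PTPN11, MYC, ZEB1, LIN28B, ERBB2, ERBB3 and CDH1 are always named. For the average contrast, the 12 largest increases and 12 largest decreases past the threshold were taken, with all 4 SHP2 miR arrays on the same side of both controls. For each other contrast, the 5 largest in each direction were taken. From each list, up to 4 passing members were taken by smallest p, or up to 2 members as values where none passed.

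Both SHP2 miR comparisons use the same control arrays. Their overlap, covariance and correlation were therefore set beside 100 simulations of unchanged groups against shared controls. The fit was tested on simulated data with known changes in the 18377 genes. For the average contrast it recovered 76.1% of genes changed by 1 log2 unit and 4.48% of those changed by 0.5, with 12 unchanged genes called. For SHP2 miR2 alone it recovered 46.3% of genes changed by 1 log2 unit, and for SHP2 miR1 alone 61.2%. Both SHP2 miRs were simulated with the same changes and the same spread. These shares therefore differ only through random draws and show no difference in power between the SHP2 miRs. In a simulated S phase list lowered by 0.5, the list test called that list and 0 others of 38. The simulated genes varied independently, so that check could not show list calls that arise from correlation between genes.

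Alternatives were a mean-variance trend or a robust prior, leaving out dim genes (mean value at or below the 40th percentile of probe sets), quantile normalization, centring on array medians, averaging probe sets, testing all probe sets, array weights, fits on only the groups compared, a replicate block, a minimum log2 difference of 1, and leaving out each array. Where 1 array of a group was left out, its remaining array was assumed to vary like the other groups. Cyclic loess normalization, removal of a trend over gene span and leaving PTPN11 out of the lists were added after seeing the data. Gene span was the genomic length in the RefSeq table of assembly GRCh38.p14, known for 99.8% of genes. Figures were drawn with matplotlib 3.10.9.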

Results

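The series compared MCF10A-HER2/3 mammary epithelial cells in three-dimensional culture with and without reduction of SHP2, a tyrosine phosphatase encoded by PTPN11 that acts downstream of receptor tyrosine kinases. Doxycycline was given for 15 days to induce either of 2 SHP2 miRs, named SHP2 miR1 and SHP2 miR2, or a control miR. Each group had 2 arrays, and 18377 genes were tested. The design asks which transcripts differ when SHP2 is reduced, and whether both SHP2 miRs give the same differences.

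PTPN11, on chromosome 12, was lower on all 4 SHP2 miR arrays than on either control. Its value was 8.20 ± 0.34 in control, 5.88 ± 0.23 with SHP2 miR1 and 7.09 ± 0.27 with SHP2 miR2 (log2, mean ± SD, n = 2 each). Averaged over both SHP2 miRs it fell by 1.72 on the log2 scale (SE 0.19, 3.28-fold, adjusted p = 0.00184). With SHP2 miR1 it fell by 2.32 (SE 0.22, adjusted p = 0.000548). With SHP2 miR2 the difference was -1.11 (2.16-fold), which did not pass the threshold over all genes (adjusted p = 0.0813). The difference between the SHP2 miRs was 1.21, with a 95% interval of 0.73 to 1.70, and did not pass either (adjusted p = 0.0645). With each array left out in turn, the average difference lay between -1.95 and -1.48 and stayed past the threshold.

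Of the other genes fixed in advance, ERBB3 fell by 1.35 (SE 0.13, 2.54-fold, adjusted p = 0.000959), with -1.54 for SHP2 miR1 and -1.16 for SHP2 miR2. The probe set cannot tell an introduced ERBB3 from the cells' own. ERBB2 had an average difference of -0.38 (adjusted p = 0.136), with -0.64 for SHP2 miR1, which passed (adjusted p = 0.0310), and -0.12 for SHP2 miR2 (adjusted p = 0.819). The differences of MYC, at -0.05 (adjusted p = 0.866), and of CDH1, the gene of E-cadherin, at 0.00 (adjusted p = 0.992), did not pass. ZEB1, a repressor of epithelial genes, had -0.44 (adjusted p = 0.107), and LIN28B, an RNA-binding protein that blocks let-7 maturation, had 0.10 (adjusted p = 0.794). LIN28B lay near the floor of the arrays, with a control mean of 2.57. The sign of LIN28B turned under quantile normalization and that of CDH1 under centring. With an array left out the signs of LIN28B, CDH1 and MYC also turned, with values between -0.15 and 0.24.

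**Figure D1:**
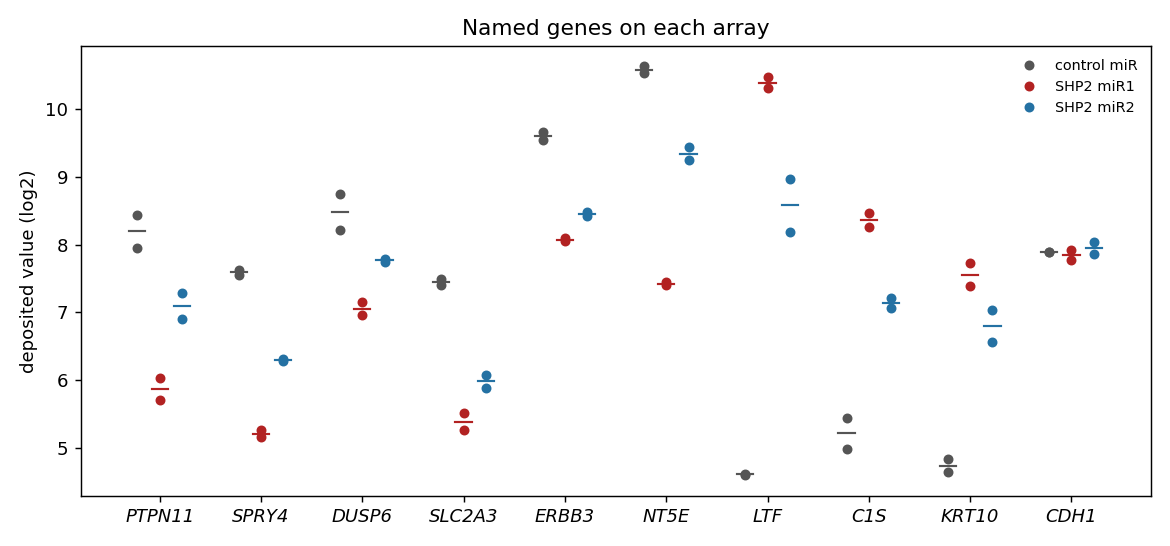
Deposited log2 value (vertical axis) of 10 named genes on each of the 6 arrays. Points are arrays, short lines are group means, and colours are the groups. PTPN11 averaged 8.20 in control, 5.88 with SHP2 miR1 and 7.09 with SHP2 miR2, while CDH1 stayed between 7.78 and 8.04 on all arrays.

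Averaged over both SHP2 miRs, 771 genes passed the threshold, of which 281 were higher and 490 lower than in control. The largest increase was in LTF, the iron-binding milk protein lactoferrin, at 4.88 (SE 0.20, 29.4-fold, adjusted p = 2.84e-05). The complement proteases C1S and C1R rose by 2.54 (SE 0.16) and 2.05 (SE 0.13). The keratins KRT10 and KRT16 rose by 2.44 (SE 0.18) and 2.07 (SE 0.14). Among secreted proteins, CHI3L1 rose by 2.23, the lung collectin SFTPD by 2.06 and the acute-phase protein SAA2 by 1.92. The enzymes ADH1B and CYP1B1 rose by 2.18 and 1.93, CCDC69 by 1.91 and the transcription factor ETS2 by 1.86. ADH1B, KRT16 and SAA2 have close paralogs whose transcripts may bind the same probes.

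The largest decreases were in CHRNA9, a nicotinic receptor subunit, which fell by 2.79 (SE 0.16, 6.90-fold, adjusted p = 0.000123), and the ammonium transporter RHCG, which fell by 2.67 (SE 0.19, 6.35-fold). PRDM1, a transcriptional repressor, fell by 2.28. NT5E, the ecto-nucleotidase CD73, fell by 2.20 and the receptor subunit GABRA2 by 2.17. RPSAP52, SPRY4, AQP9 and the glucose transporter SLC2A3 fell by 1.97, 1.84, 1.83 and 1.76. SPINK6, RP1 and the epidermal protease CASP14 fell by 1.75, 1.73 and 1.73. All 24 genes of these sets of 12 lay beyond both controls on all 4 SHP2 miR arrays, as the rule required. They stayed past the threshold with any array left out.

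The count of 771 rested on both controls. It was 185 without control replicate 1 and 108 without control replicate 2. Without SHP2 miR1 replicate 1 or 2 it was 452 or 470, and without SHP2 miR2 replicate 1 or 2 it was 392 or 512. At an unadjusted p under 0.05 there were 3839 genes, against 919 by chance. The controls were not alike in their distance from the SHP2 miR arrays. Control replicate 2 correlated with the SHP2 miR1 arrays at r = 0.958 and 0.960, and control replicate 1 at 0.971 and 0.972. With the SHP2 miR2 arrays the values were 0.978 and 0.983 for control replicate 2, and 0.982 and 0.983 for control replicate 1. Of the 771 genes, 192 differed by at least 1 log2 unit, 70 of them higher and 122 lower. Called genes that fell spanned a median of 67.9 kb in the genome and those that rose 18.9 kb, against 24.5 kb for all genes. With the trend over gene span removed, 652 genes passed (270 higher and 382 lower), of which 601 were among the 771.

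Transcripts that report ERK pathway activity fell with the SHP2 miRs. Of 24 measured members of that list, 11 fell and 0 rose, with a list median of -0.63 (camera adjusted p = 4.05e-10; adjusted p = 0.126 with an estimated correlation). Adjusted over the list alone, 17 were lower and 1 higher. SPRY4, an ERK feedback inhibitor, fell by 1.84 (SE 0.13, 3.57-fold). The ERK phosphatases DUSP4 and DUSP6 fell by 1.21 (SE 0.14) and 1.06 (SE 0.17), and IER3 by 0.88 (SE 0.14). With SHP2 miR1 alone 16 of the 24 fell (median -0.90), and with SHP2 miR2 alone 1 fell (median -0.28, camera adjusted p = 1.26e-06; adjusted p = 0.215 with an estimated correlation). With an array left out, DUSP4, IER3 and DUSP6 reached adjusted p-values of up to 0.0558, 0.109 and 0.126, for DUSP4 and DUSP6 without control replicate 2 and for IER3 without either control.

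Among 15 ERBB receptors and EGF-family ligands, 3 fell and 0 rose. These were ERBB3 and the ligands EREG and TGFA, which fell by 1.38 (SE 0.13) and 1.16 (SE 0.12). The list median was -0.02 and its mean -0.30 (camera adjusted p = 0.0422; adjusted p = 0.317 with an estimated correlation), and 6 were lower and 0 higher when adjusted over the list alone. Of 23 SHP2 partners and RAS-ERK signalling proteins, 4 fell and 0 rose, with a median of -0.16 (camera adjusted p = 0.0387; adjusted p = 0.380 with an estimated correlation). Adjusted over the list alone, 5 were lower. PTPN11, the target of the SHP2 miRs, is a member, and without it the list did not pass (22 genes, median -0.13, camera adjusted p = 0.102; adjusted p = 0.494 with an estimated correlation). Besides PTPN11 the members that fell were RASAL2, the kinase gene MAP2K1 and the ubiquitin ligase gene CBL, at -0.83, -0.76 and -0.68. Among random lists matched on mean value, the ERBB median lay at percentile 33.8 and that of the partner list at 7.1. Brightness is therefore not excluded for either list. Without either control, RASAL2, MAP2K1 and CBL missed the threshold. MAP2K1 also missed it without replicate 2 of either SHP2 miR, and CBL with any array left out. Without control replicate 1 neither list passed, with adjusted p-values of 0.0863 and 0.0999. The ERBB list also missed the threshold without SHP2 miR2 replicate 1 (0.0538) or 2 (0.0686) and with the replicate number as a block (adjusted p = 0.0618), and the partner list without SHP2 miR1 replicate 1 (0.0518) or SHP2 miR2 replicate 2 (0.123).

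Hypoxia and glycolysis genes fell. Of 28 measured, 10 fell and 0 rose, with a median of -0.44 (camera adjusted p = 7.00e-13; adjusted p = 0.101 with an estimated correlation), and 19 were lower when adjusted over the list alone. SLC2A3 fell by 1.76 (SE 0.14, 3.39-fold) and ANGPTL4, a lipase inhibitor, by 1.46 (SE 0.14). The angiogenic factor VEGFA fell by 1.09 (SE 0.13) and the glycolytic enzyme ENO2 by 1.07 (SE 0.14). With SHP2 miR1 alone 13 of the 28 fell (median -0.59), and with SHP2 miR2 alone 3 fell (median -0.40, camera adjusted p = 1.09e-11; adjusted p = 0.134 with an estimated correlation). VEGFA and ENO2 reached 0.0558 without control replicate 2 and 0.0529 without control replicate 1.

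**Figure D2:**
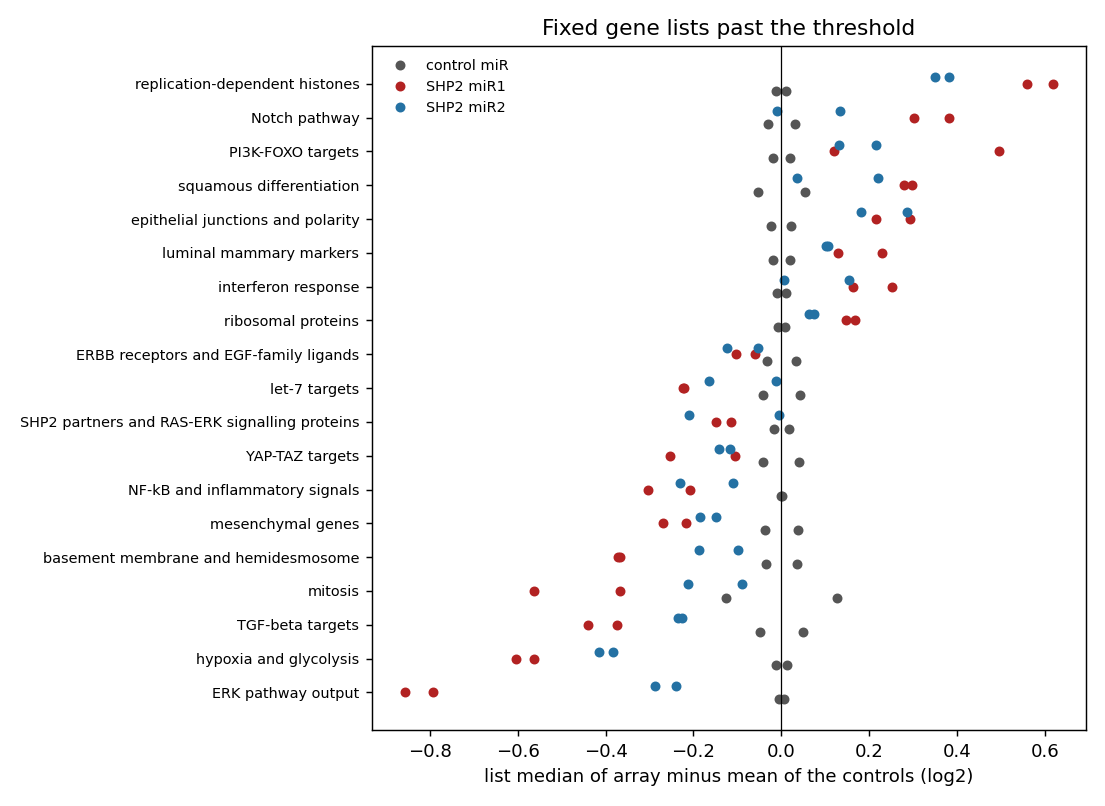
Median over each list of the array's value minus the mean of the controls (log2, horizontal axis), for the 19 fixed lists past the camera threshold. Each point is 1 array and colours are the groups. On the ERK pathway output list, the SHP2 miR1 arrays lay at -0.86 and -0.79 and the SHP2 miR2 arrays at -0.24 and -0.29.

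TGF-beta targets fell, with 5 of 27 lower, 0 higher and a median of -0.35 (camera adjusted p = 1.65e-07; adjusted p = 0.101 with an estimated correlation). Adjusted over the list alone, 6 were lower. SKIL, a SMAD co-repressor, fell by 1.38 (SE 0.13), INHBA by 1.61 (SE 0.27), PMEPA1 by 1.05 and BHLHE40 by 0.80. Of 28 mesenchymal genes, 6 fell and 0 rose, with a median of -0.23 (camera adjusted p = 0.00180; adjusted p = 0.243 with an estimated correlation), and 11 were lower over the list alone. The fibronectin receptor subunit ITGA5 fell by 1.41 (SE 0.14), the transcription factor SNAI2 by 1.27 (SE 0.16), fibronectin FN1 by 1.05 and fibrillin FBN1 by 0.98. Without control replicate 1 the mesenchymal list did not pass (median -0.25, adjusted p = 0.0826). NF-kB and inflammatory signals fell as a list, with 7 of 28 lower, 1 higher and a median of -0.20 (camera adjusted p = 0.00424; adjusted p = 0.243 with an estimated correlation). Over the list alone, 11 were lower and 2 higher. IL1B fell by 1.31, CCL20 by 1.33, CXCL8 by 0.99 and CXCL2 by 1.01. SKIL, ITGA5 and IL1B stayed past the threshold with any array left out. Without control replicate 2, adjusted p reached 0.0903 for PMEPA1, 0.0562 for FN1, 0.0681 for SNAI2, 0.0730 for FBN1, 0.0539 for CCL20 and 0.138 for CXCL8. Without either control, INHBA, BHLHE40 and CXCL2 missed the threshold at up to 0.134, 0.163 and 0.188, and CXCL2 also without SHP2 miR2 replicate 1.

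Mitosis genes fell as a list (median -0.35, camera adjusted p = 2.30e-06; adjusted p = 0.339 with an estimated correlation), although only 2 of 31 fell on their own, and 6 over the list alone. These were ANLN, an actin-binding protein of the cleavage furrow, at -1.03 (SE 0.18) and the checkpoint kinase gene BUB1 at -0.57 (SE 0.13). Without either control ANLN and BUB1 missed the threshold at up to 0.203 and 0.352, and BUB1 missed it with any array left out. In the mitosis median the controls themselves differed, with -0.13 for replicate 1 and 0.13 for replicate 2 around their mean, and SHP2 miR2 replicate 2 lay between them at -0.09. With fry the mitosis list missed the threshold (adjusted p = 0.0966). The S phase list had 0 of 30 genes past the threshold in limma, 0 when adjusted over the list alone and a median of -0.05 (camera adjusted p = 0.598; adjusted p = 0.847 with an estimated correlation), with 0.42 for CDT1 and -0.42 for DTL as the members of smallest p. Replication-dependent histone genes rose, with 6 of 17 higher, 0 lower and a median of 0.46 (camera adjusted p = 3.46e-08; adjusted p = 0.101 with an estimated correlation). Over the list alone, 11 were higher. H2BC9 rose by 0.91 (SE 0.15), H4C4 by 0.84, H1-5 by 0.82 and H3C7 by 0.72, and without either control they missed the threshold at up to 0.149, 0.156, 0.134 and 0.230. H1-5 and H3C7 also missed it without some of the SHP2 miR arrays. Histone genes are close copies of each other, so a probe set can bind more than 1 of them.

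Epithelial junction and polarity genes rose, with 4 of 29 higher, 0 lower and a median of 0.15 (camera adjusted p = 0.00180; adjusted p = 0.339 with an estimated correlation). Over the list alone, 9 were higher and 1 lower. The desmosomal cadherins DSG3 and DSC3 rose by 0.70 (SE 0.16) and 0.68 (SE 0.13), claudin CLDN1 by 0.66 and the transcription factor OVOL1 by 0.65. Without either control, and without most of the other arrays, these 4 missed the threshold at up to 0.174, 0.119, 0.149 and 0.275. Squamous differentiation genes rose as a list, with 5 of 33 higher, 1 lower and a median of 0.16 (camera adjusted p = 0.00201; adjusted p = 0.339 with an estimated correlation). Over the list alone, 6 were higher and 3 lower. Besides KRT10 and KRT16, the cornified envelope gene SPRR1B rose by 0.99 (SE 0.14), while RHCG fell. SPRR1B did not pass without either control, at adjusted p-values of up to 0.0868, and the squamous list did not pass with fry (adjusted p = 0.0939).

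Interferon response genes rose as a list, with 4 of 36 higher, 1 lower and a median of 0.14 (camera adjusted p = 0.0387; adjusted p = 0.339 with an estimated correlation). Adjusted over the list alone, 6 were higher and 3 lower. The antiviral genes OAS1, IFITM1 and IFI44L rose by 1.25, 1.12 and 1.01, and SAMD9 fell by 1.12. OAS1 held with any array left out, while IFITM1 reached 0.0874 without control replicate 2 and IFI44L 0.0605 without control replicate 1. SAMD9 reached up to 0.255 without control replicate 2, SHP2 miR1 replicate 1 or SHP2 miR2 replicate 1. The list itself missed the threshold without control replicate 1 (0.0826), SHP2 miR1 replicate 2 (0.0905) and SHP2 miR2 replicate 2 (0.121).

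PI3K-FOXO targets, which FOXO factors induce when AKT is inactive, had 7 of 26 higher, 3 lower and a median of 0.24 (camera adjusted p = 0.0441; adjusted p = 0.317 with an estimated correlation). Adjusted over the list alone, 12 were higher and 5 lower. The ubiquitin ligase gene FBXO32, the kinase gene PDK4 and the death ligand TNFSF10 rose by 1.73, 1.64 and 1.32, and ERBB3 fell. TNFSF10 reached 0.0539 without control replicate 2. The list missed the threshold without control replicate 1 (0.0983), SHP2 miR1 replicate 1 (0.0572) and SHP2 miR2 replicate 1 (0.0726) or 2 (0.0686). With dim genes left out its median was 0.08 and it missed the threshold too (0.0549).

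Among 23 Notch pathway genes the receptors moved apart, with NOTCH1 at 0.80 and NOTCH2 at -0.65. The list had 1 higher, 1 lower and a median of 0.28 (camera adjusted p = 0.0432; adjusted p = 0.380 with an estimated correlation), and 3 higher and 2 lower when adjusted over the list alone. NOTCH1 reached 0.143 without either control, and NOTCH2 missed the threshold with any array left out, at up to 0.239. The list missed it without control replicate 1 (0.0540) or 2 (0.121), SHP2 miR1 replicate 1 (0.0819) and SHP2 miR2 replicate 1 (0.0827). Luminal mammary markers had LTF as their only passing member of 30, with 0 lower and a median of 0.14 (camera adjusted p = 0.0387; adjusted p = 0.339 with an estimated correlation), and 3 higher and 2 lower when adjusted over the list alone. They missed the threshold without control replicate 2 (0.100). Ribosomal proteins had 0 of 24 members past the threshold in limma, 0 when adjusted over the list alone and a median of 0.11 (camera adjusted p = 0.0385; adjusted p = 0.317 with an estimated correlation). The members of smallest p, RPLP2 and RPLP1, had 0.35 and 0.34, and the list reached 0.106 without control replicate 1.

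YAP-TAZ targets fell as a list, with 6 of 26 lower, 1 higher and a median of -0.19 (camera adjusted p = 0.0387; adjusted p = 0.317 with an estimated correlation). Adjusted over the list alone, 8 were lower and 4 higher. Besides NT5E, tissue factor F3 fell by 1.26, FSTL1 by 1.01 and ASAP1 by 0.91. Without control replicate 2 ASAP1 reached 0.103, and without either control FSTL1 reached up to 0.142. The list missed the threshold without control replicate 1 (0.0863), SHP2 miR1 replicate 1 (0.0563) and SHP2 miR2 replicate 1 (0.0578).

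Basement membrane and hemidesmosome genes had 2 of 22 lower, 1 higher and a median of -0.27 (camera adjusted p = 0.00919; adjusted p = 0.317 with an estimated correlation), and 5 lower and 1 higher when adjusted over the list alone. The laminin chain LAMB3 fell by 1.07 and the integrin activator FERMT1 by 0.88, and LAMB1 rose by 0.65. FERMT1 reached 0.149 without control replicate 2, and LAMB1 missed the threshold with any array left out, at up to 0.147. Targets of let-7 had IGF2BP2, an RNA-binding protein, as the only passing member of 29, at -0.61, with 0 higher, 1 lower over the list alone and a median of -0.15 (camera adjusted p = 0.0387; adjusted p = 0.437 with an estimated correlation). IGF2BP2 missed the threshold with any array left out, at up to 0.221. The list missed it without control replicate 2 (0.121), SHP2 miR1 replicate 1 (0.0695) and SHP2 miR2 replicate 2 (0.174).

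Ribosomal proteins reached the largest adjusted p of the 19 lists when the trend over gene span was removed. In that fit, 8 of the 19 lists missed the threshold. These were ribosomal proteins (median 0.06, adjusted p = 0.390), the SHP2 partner list (-0.04, 0.105), the ERBB list (-0.01, 0.103), let-7 targets (-0.12, 0.103), the Notch list (0.23, 0.103), basement membrane genes (-0.22, 0.0646), luminal markers (0.17, 0.0577) and PI3K-FOXO targets (0.22, 0.0567). After quantile normalization, luminal (0.0585), interferon (0.0526), let-7 (0.0529), YAP-TAZ (0.0774) and SHP2 partner (0.124) lists missed it. With dim genes left out, 14 lists passed, and let-7 (0.101), PI3K-FOXO, YAP-TAZ, Notch and SHP2 partner lists (each 0.0549) missed the threshold. Without control replicate 1, 12 lists passed, of which 11 were among the 19. With an estimated correlation 0 of 38 lists passed. The estimate was 0.00112 for the hypoxia list, -0.0532 for histones, -0.0151 for TGF-beta targets and -0.0157 for the NF-kB list. These values lie below the preset 0.01, so a higher correlation did not end those calls. For the hypoxia list the unadjusted camera p was 1.84e-14 at the preset and 0.00341 with the estimate, on only 3 residual degrees of freedom. Other lists had estimates above the preset, such as ERK pathway output (0.0426) and mitosis (0.251). At an unadjusted p under 0.05, camera with the estimated correlation found the hypoxia, histone, TGF-beta, ERK, NF-kB and mesenchymal lists (p = 0.00341, 0.00770, 0.00798, 0.0132, 0.0341 and 0.0383), and fry found 15 lists after adjustment, 14 of them among the 19. With fry the squamous (0.0939), interferon (0.0672), let-7 (0.139), Notch (0.0966) and mitosis (0.0966) lists missed the threshold.

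Of the other 19 lists, which did not pass, basal and myoepithelial markers had 2 of 19 higher, 0 lower and a median of 0.05 (camera adjusted p = 0.270; adjusted p = 0.416 with an estimated correlation), and 3 higher and 1 lower when adjusted over the list alone. The basal keratins KRT15 and KRT14 rose by 1.82 (SE 0.13) and 1.10 (SE 0.14), and KRT14 reached 0.0855 without control replicate 2. The stem and progenitor list had INHBA as its only passing member of 22, with a median of 0.08 and a mean of -0.06 (camera adjusted p = 0.958; adjusted p = 0.961 with an estimated correlation), and 4 lower when adjusted over the list alone. INHBA reached up to 0.134 without either control. STAT3 targets had 2 of 21 higher, 1 lower and a median of 0.17 (camera adjusted p = 0.0731; adjusted p = 0.494 with an estimated correlation), and 4 higher and 4 lower when adjusted over the list alone. SERPINA3 and BCL6 rose by 1.25 and 1.15 and the survival factor MCL1 fell by 0.87, with BCL6 at 0.0616 without control replicate 1 and MCL1 at up to 0.133 without either control. The p53 targets had 3 of 27 higher, 0 lower and a median of 0.08 (camera adjusted p = 0.131; adjusted p = 0.416 with an estimated correlation), and 4 higher when adjusted over the list alone. SESN1, GDF15 and DDB2 rose by 0.76, 0.79 and 0.75, and missed the threshold without either control. GDF15 also missed it without SHP2 miR1 replicate 1, and DDB2 without SHP2 miR1 replicate 2 or SHP2 miR2 replicate 1.

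MYC targets, ribosome biogenesis genes among them, had 0 of 26 past the threshold in limma, 0 when adjusted over the list alone and a median of -0.06 (camera adjusted p = 0.570; adjusted p = 0.724 with an estimated correlation). Their members of smallest p, ODC1 and FBL, had 0.48 and 0.38. Heat shock genes had 0 of 16, 0 over the list alone and a median of -0.20 (camera adjusted p = 0.0731; adjusted p = 0.368 with an estimated correlation), with CHORDC1 at -0.55 and HSP90AA1 at -0.37. Wnt targets had 1 of 25 higher, 2 lower and a median of 0.10 (camera adjusted p = 0.607; adjusted p = 0.667 with an estimated correlation), and the same counts when adjusted over the list alone. WNT5A fell by 1.18 and DKK1 by 0.62, and SFRP1 rose by 0.65. WNT5A missed the threshold without either control, and DKK1 and SFRP1 with any array left out. Extracellular proteases and inhibitors had 1 of 28 higher, 4 lower and a median of -0.07 (camera adjusted p = 0.155; adjusted p = 0.532 with an estimated correlation), and 1 higher and 8 lower when adjusted over the list alone. PLAU, the gene of urokinase, fell by 1.12, SERPINB5 by 0.89 and ADAM12 by 0.76, and the lysosomal protease CTSD rose by 0.82. Only PLAU held with any array left out, and the others missed the threshold without either control. ADAM12 also missed it without SHP2 miR1 replicate 1 or either SHP2 miR2 array.

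Cholesterol synthesis and uptake genes had 0 of 19 higher, 2 lower and a median of -0.06 (camera adjusted p = 0.321; adjusted p = 0.437 with an estimated correlation), and 2 higher and 3 lower when adjusted over the list alone. The sterol enzymes MSMO1 and SC5D fell by 0.79 and 0.56. SC5D missed the threshold with any array left out, and MSMO1 without either control or SHP2 miR2 replicate 1. Fatty acid synthesis genes had 1 of 18 higher, 1 lower and a median of 0.06 (camera adjusted p = 0.520; adjusted p = 0.620 with an estimated correlation), and 2 higher and 2 lower when adjusted over the list alone. ME1, which makes NADPH, fell by 0.88 and LPIN1 rose by 0.75, and both missed the threshold without either control. LPIN1 also missed it without replicate 2 of either SHP2 miR. The unfolded protein and ATF4 response had 1 of 29 higher, 1 lower and a median of -0.08 (camera adjusted p = 0.225; adjusted p = 0.542 with an estimated correlation), and 2 higher and 4 lower when adjusted over the list alone. VLDLR fell by 1.44 and the amino acid transporter SLC7A5 rose by 0.92, the latter at up to 0.0743 without either control. NRF2 targets had 2 of 22 higher, 2 lower and a median of 0.06 (camera adjusted p = 0.520; adjusted p = 0.713 with an estimated correlation), and 5 higher and 3 lower when adjusted over the list alone. The exporter ABCC2 and the reductase AKR1B10 rose by 1.33 and 1.08, and GCLC, of glutathione synthesis, fell by 0.83. Without either control AKR1B10 and GCLC missed the threshold, as both did without SHP2 miR1 replicate 1. GCLC also missed it without SHP2 miR1 replicate 2 or SHP2 miR2 replicate 1.

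Autophagy and lysosome genes had 1 of 25 higher, 1 lower and a median of -0.03 (camera adjusted p = 0.676; adjusted p = 0.788 with an estimated correlation), and 2 higher and 1 lower when adjusted over the list alone. ATG16L1 fell by 1.12, at 0.0731 without control replicate 2. Oxidative phosphorylation genes had 1 of 27 higher, 0 lower and a median of 0.05 (camera adjusted p = 0.155; adjusted p = 0.355 with an estimated correlation), and 2 higher when adjusted over the list alone. COX5B, of complex IV, rose by 0.69 and missed the threshold with any array left out, at up to 0.289.

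Markers of cell types other than epithelium served as a background. Their medians of 0.11 to 0.12 were close to those of some rising lists that passed. These were ribosomal proteins (0.11), luminal markers (0.14), interferon response (0.14), epithelial junctions (0.15) and squamous differentiation (0.16). Among random lists matched on mean value, the background lists lay at percentiles 73.9 to 88.0, and those rising lists at 98.7 to 99.9. Fibroblast markers had 0 of 15 and a median of 0.11 (camera adjusted p = 0.307; adjusted p = 0.437 with an estimated correlation), with FAP at 0.45 and THY1 at 0.33. Adipocyte markers had 0 of 12 and a median of 0.11 (camera adjusted p = 0.156; adjusted p = 0.368 with an estimated correlation), with PLIN4 at 0.30 and CFD at 0.29, and both lists had 0 when adjusted over the list alone. Leukocyte markers had 0 of 15 higher, 1 lower and a median of 0.12 (camera adjusted p = 0.327; adjusted p = 0.562 with an estimated correlation), and 1 higher and 1 lower when adjusted over the list alone. Endothelial markers had 1 of 14 higher, 1 lower and a median of 0.12 (camera adjusted p = 0.447; adjusted p = 0.532 with an estimated correlation), with the same counts when adjusted over the list alone. The receptor genes TEK and CSF1R fell by 1.38 and 0.75. PECAM1 rose by 0.60 on the probe set used, while its dimmer probe set had -0.07. TEK held with any array left out, while PECAM1 missed the threshold with any array left out. CSF1R missed it without either control, either SHP2 miR1 array or SHP2 miR2 replicate 2.

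SHP2 miR1 gave more calls than SHP2 miR2. With SHP2 miR1, 1581 genes passed (489 higher and 1092 lower), and after centring on array medians the split was 378 higher and 1536 lower. With SHP2 miR2, 68 passed (35 higher and 33 lower). At an unadjusted limma p under 0.05 the counts lay closer, with 5169 genes for SHP2 miR1 and 2025 for SHP2 miR2, against 919 by chance for each. The largest increases were in LTF for both, at 5.78 (55.1-fold) and 3.97 (15.7-fold), with C1S and KRT10 also among the top 5 of both. Decreases were led by RHCG at -3.75 with SHP2 miR1 and by CHRNA9 at -2.05 with SHP2 miR2. TLR2 and HTR1D, which fell by 1.72 and 1.54 with SHP2 miR2, were at -1.53 and -1.48 with SHP2 miR1. Without control replicate 2 the SHP2 miR1 count was 269, and without its own replicate 1 or 2 it was 465 or 473. The SHP2 miR2 count was 0 in limma without either control, with 2108 genes (control replicate 1 left out) and 1503 genes (control replicate 2 left out) at an unadjusted p under 0.05. It was 4 or 1 without its own replicate 1 or 2.

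Nearly all genes called with SHP2 miR2 were also called with SHP2 miR1, LTF, C1S and CHRNA9 among them, while most SHP2 miR1 calls were not called with SHP2 miR2. Even so, 96.5% of the SHP2 miR1 calls had the same sign with SHP2 miR2, a share that the shared controls can raise. Of the 68 genes called with SHP2 miR2, 67 were also called with SHP2 miR1 in the same direction (35 higher and 32 lower), and 0 in opposite directions. Independent lists of these sizes would share 0.93 higher and 1.96 lower genes. Simulated unchanged groups against shared controls shared 0.02 on average and 1 at most. No gene was changed in these simulations, so hardly any could be called in either comparison. Their shared count therefore cannot show how many real calls coincide through the shared controls. Across genes the covariance of the log2 differences was 0.0757, against 0.0170 in the simulation, a difference of 0.0587 with a jackknife SE of the covariance over arrays of 0.0430, and the correlation was 0.668 against 0.5. Genes are not independent replicates, and part of the excess in shared calls may come from the shared controls. The shared count was 0 without either control and 4 or 1 without SHP2 miR2 replicate 1 or 2. Other settings gave 31 calls with SHP2 miR2 and 31 shared (all probe sets), 37 and 36 (replicate block), 154 and 150 (dim genes left out) and 367 and 348 (mean-variance trend in the prior).

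**Figure D3:**
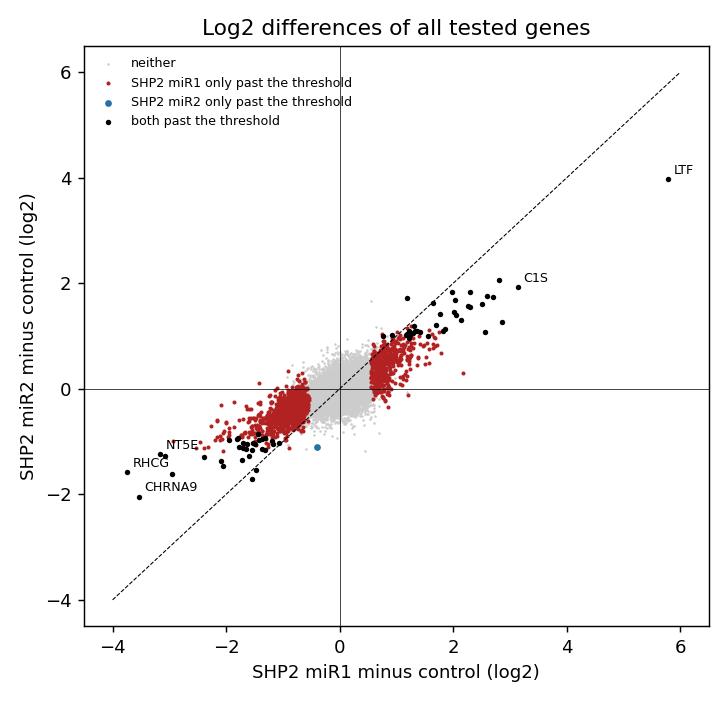
Log2 difference of SHP2 miR2 from control (vertical axis) against that of SHP2 miR1 (horizontal axis) for the 18377 tested genes. Black points passed the threshold for both (67 genes), red for SHP2 miR1 only, blue for SHP2 miR2 only (1 gene) and grey for neither, and the dashed line marks equal differences.

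Tested directly, 35 genes differed between the SHP2 miRs, 28 higher with SHP2 miR2 and 7 lower. RHCG was 2.16 higher with SHP2 miR2 (4.47-fold, adjusted p = 0.00545), followed by RPSAP52 (1.94), NT5E (1.92), GABRA2 (1.797) and ITPKA, an inositol kinase (1.79). The first 4 of these were among the largest decreases of the average, and ITPKA was at -2.09 with SHP2 miR1 and -0.30 with SHP2 miR2. BBOX1, of carnitine synthesis, was lower with SHP2 miR2 by -1.87, LTF by -1.81, SFTPD by -1.60, MIR600HG by -1.53 and KRT15 by -1.48. BBOX1 was at 2.17 with SHP2 miR1 and 0.30 with SHP2 miR2. MIR600HG was at 0.69 and -0.84, neither past the threshold. The count was 12 without either control, 15 or 11 without SHP2 miR1 replicate 1 or 2, and 0 or 10 without SHP2 miR2 replicate 1 or 2. Where it was 0 in limma, 2671 genes had an unadjusted p under 0.05. It was 11 when all probe sets were tested, 12 with the replicate number as a block, 55 with array weights, 69 after centring on array medians, 95 with dim genes left out and 446 with a mean-variance trend in the prior.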

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

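The sign test on the ERK list was chosen after its result was seen, and the control split in the other order and the gene span values were added after seeing the data. The bounds of the other tests were written after the patterns were seen and before the tests were run, were once replaced by looser ones after results were known, and were then restored word for word, so that the values here are held to the original bounds, except that the spread between replicates is not used to exclude variation between cultures.

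Some results differed between the SHP2 miRs when the difference itself was tested. In 35 genes the log2 difference between SHP2 miR2 and SHP2 miR1 passed the threshold, including RHCG (2.16), RPSAP52 (1.94), NT5E (1.92), GABRA2 (1.797) and ITPKA (1.79), and in the other direction BBOX1 (-1.87), LTF (-1.81), SFTPD (-1.60), MIR600HG (-1.53) and KRT15 (-1.48). As lists, 7 of 38 passed camera at the preset correlation, all with a higher median with SHP2 miR2. These were ERK pathway output (0.41), mitosis (0.28), cholesterol synthesis and uptake (0.25), basement membrane and hemidesmosome (0.24), TGF-beta targets (0.17), hypoxia and glycolysis (0.15) and MYC targets (0.12). With an estimated correlation 0 of these passed, with adjusted p-values of 0.308 to 0.423, and with fry mitosis (0.206) and MYC targets (0.128) missed the threshold. The difference between the SHP2 miRs rose with mean value (Spearman correlation 0.275, and 0.0623 after quantile normalization). Among random lists matched on mean value, the medians lay at percentile 71.7 for MYC targets, 92.0 for hypoxia, 96.0 for TGF-beta targets, 98.8 for cholesterol and 99.6 or higher for the others, so brightness is not excluded for the first 3. Probe sets that the report does not use were counted too. Of the 7807 probe sets without a gene name here, 52 passed for the average of both SHP2 miRs, adjusted over all 28869 probe sets. With that adjustment 449 of the 18377 named genes passed, a larger share.

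More genes passed with SHP2 miR1 (1581) than with SHP2 miR2 (68), and at an unadjusted limma p under 0.05 there were 5169 and 2025. A narrower spread of values on the SHP2 miR1 arrays is argued against, since after quantile normalization the counts still stood in a ratio of 20.2. Targets of SHP2 miR1 other than PTPN11 were tested as the main source of the calls, and the first share below met the bound set against them. Of 183 genes called with SHP2 miR1 against control replicate 1 alone, fitted on those 3 arrays without the SHP2 miR2 group, 99.5% had the same sign with SHP2 miR2 against control replicate 2 alone, and with the controls exchanged 81.8% of 972 genes did, against 66.9% of all genes. The share over all genes was taken in the first order only. A difference of the controls from both SHP2 miR groups would also give shared signs, so these shares cannot settle the source of the calls. The first share also met the bound for a deeper reduction of PTPN11 by SHP2 miR1. An equal reduction by both would give shared signs too, so the share cannot tell the depth. A deeper reduction as the source of the calls remains a hypothesis. PTPN11 itself was 1.21 higher with SHP2 miR2 than with SHP2 miR1 (log2), with a 95% interval of 0.73 to 1.70. Adjusted over all genes, this difference missed the threshold (limma adjusted p = 0.0645). Other targets remain open, also for single genes such as MIR600HG, whose values had opposite signs.

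Hypoxia and glycolysis genes had a lower median with each SHP2 miR (-0.59 and -0.40), although only 3 of 28 passed alone with SHP2 miR2 and neither list call held with an estimated correlation. A loss of signal of bright probe sets is argued against, since the list median lay at percentile 0.00 of 10000 random lists matched on mean value, and so is a deviating control array, since without either control the list kept at least 87.7% of its median. The largest shift between replicates of a group was 10.9% of the average shift. Since nothing says that the replicates were separate cultures, that value does not exclude variation between cultures, and a difference in density or oxygen between groups stays open. Whether the lower values follow from lower SHP2 is therefore left open.

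ERK pathway output genes had a lower median with each SHP2 miR (-0.90 and -0.28), although only 1 of 24 passed alone with SHP2 miR2 and neither list call held with an estimated correlation (adjusted p = 0.128 and 0.215). Their average median lay at percentile 0.00 of the matched random lists, and without either control the list kept at least 92.8% of it, which argues against bright probe sets and against a deviating control. With the trend over gene span removed, the median was -0.53. With SHP2 miR2, where the PTPN11 mean was higher, 20 of 24 members were higher (median difference 0.41, exact sign test p = 0.00154, two-sided), but the test was chosen after these medians were seen and its members are not independent, so it adds no evidence for a graded response to PTPN11. As 2 levels of reduction come from constructs of different sequence, the amount and the construct were not separated by the design and a graded response stays open.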

How the results depend on the processing

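PTPN11 stayed lower and past the threshold under every alternative run, at -1.95 to -1.48 with an array left out. Cyclic loess, the gene span trend and lists without PTPN11 were added after seeing the data, and where no construction is named the cause was not tested. With a mean-variance trend in the prior, calls rose to 1793 for the average, 2786 for SHP2 miR1, 367 for SHP2 miR2, 348 the same way by both and 446 between the SHP2 miRs. Without dim genes (fewer tests and a refitted prior) SHP2 miR2 had 154, both 150 and their difference 95. Centring gave 69 for the difference and array weights 55. Testing all probe sets (more tests and a prior fitted to all of them) gave 449, 880, 31, 31 and 11 in the order above. There, 3549 genes had an unadjusted limma p under 0.05 for the average, against 3839 in the main fit, so the number of tests was not the only change. A minimum of 1 log2 unit gave 192 for the average and 435 for SHP2 miR1.

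The labels do not say whether arrays of the same replicate number were handled together. Replicate differences of the groups correlated at 0.07, 0.14 and 0.01, which neither shows nor excludes such a pairing. With the replicate number as a block, SHP2 miR2 had 37 calls, both 36 and the difference 12, the average 817 and SHP2 miR1 1709, and 18 lists passed.

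Leaving out each array in turn (fewer samples) gave 108 to 512 calls for the average, 269 to 1308 for SHP2 miR1, 0 to 60 for SHP2 miR2, 0 to 56 the same way by both and 0 to 15 for the difference. At the limma counts of 0, unadjusted p under 0.05 gave 2108 and 1503 genes for SHP2 miR2 (without control replicate 1 or 2) and 2671 for the difference (without SHP2 miR2 replicate 1). The covariance ranged from 0.0684 to 0.125, the highest without control replicate 1. Lists past the threshold numbered 12 to 18 in these fits, 14 without dim genes, 18 without PTPN11 in the lists, 12 with the gene span trend removed, 0 with an estimated correlation and 15 with fry. Quantile normalization and cyclic loess each gave 17 lists, 9 up and 8 down against 8 and 11, and 14 were among the 19.

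Reversed signs occurred in 3 genes that never passed. LIN28B was -0.0108 after quantile normalization and -0.0465 to 0.243 with an array left out. CDH1 was -0.0340 after centring and -0.0402 to 0.0471 with an array left out, and MYC -0.146 to 0.0444. Leaving aside the fits on only the groups compared and the minimum log2 difference, 2244 of 2561 values of named genes kept direction and side of the threshold, 302 lost the call, 7 gained one and 8 reversed, and of 323 list values 272 kept it and 51 lost it, not counting the estimated correlation, which ended all 19 list calls, and fry, which ended 5. Of 105 named genes past the threshold for the average, 43 stayed there with any array left out. Values near the floor limit what could be seen for dim genes such as LIN28B.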

Other observations

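The groups below were chosen after their values were seen. Beyond C1R and C1S, the complement genes C1RL and CFB rose by 0.72 and 1.45, while CD59, which blocks the terminal complex, fell by 0.74. Of 15 complement genes measured, 4 rose and 1 fell, with a median of 0.24. Genes of antigen processing had a median of 0.36, with 5 of 15 higher and 0 lower. The peptide transporter TAP1 rose by 0.89, the tapasin relative TAPBPL by 0.80, the immunoproteasome subunits PSMB9 and PSMB8 by 1.16 and 0.66 and BTN3A3 by 1.23.

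Alcohol and aldehyde dehydrogenases had 5 of 11 higher and 0 lower, with ADH1C at 1.28, ADH1A at 1.03, ALDH3A1 at 1.25 and ALDH3A2 at 0.71 besides ADH1B. The ADH1 genes are near-identical copies, so their values are not independent. Among 26 integrin genes, ITGA5, ITGAV and ITGB6 fell by 1.41, 0.68 and 0.77 and 0 rose, with a median of -0.03. Small nucleolar RNAs had 10 of 176 higher and 4 lower, with a median of 0.07.

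Across genes, the average log2 difference fell with gene span (Spearman correlation -0.235 over 18349 genes). In the fifth of genes with the shortest span, 73 calls were higher and 31 lower, and in the fifth with the longest span 51 were higher and 206 lower. The correlation was -0.244 after cyclic loess normalization and -0.236 without the members of the fixed lists. It was -0.267 without control replicate 1 and -0.137 without control replicate 2. Between the controls, replicate 2 minus replicate 1 correlated with span at 0.219, close in size to the group difference, against 0.0536 and 0.0723 within the SHP2 miR groups. The correlation with mean value was -0.247, against -0.0172 after quantile normalization.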
